A study of Escherichia coli K-12 with 2 samples.

How the data were processed

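RNA that stayed on an affinity column was compared between 2 libraries of *Escherichia coli* K-12 MG1655 that carried the rne131 allele and lacked the chromosomal ryhB gene. Per the labels' protocols, 0.1% arabinose was added for 10 min at an OD600 of 0.5 to induce either RyhB with an MS2 tag (group MS2-RyhB) or RyhB without the tag (group RyhB, the control). RyhB is a small RNA made when iron is scarce. It pairs with mRNAs with the help of the RNA chaperone Hfq. The MS2 tag is a phage RNA hairpin bound by the MS2 coat protein, which was fused to maltose-binding protein and held on amylose resin. Cleared lysate was passed over the resin, bound RNA was eluted with maltose and treated with DNase, and libraries were made with the ScriptSeq kit. The aligner, the counting tool, the genome build, the annotation and any filter are not given in the sources used here.

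The deposited table lists 4362 genes or regions. Of these, 2136 carry positive and 2226 negative values, the sign following the strand and never differing between the libraries. Per the file headers its first pair of value columns holds reads, but the values were treated as a score of the authors with no stated scale, because they behave as summed per-base coverage. Multiples of 25 made up 41.4% of the 476 MS2-RyhB values between 25 and 500, and 40.2% of the 751 control values in that range, against 4.0% by chance. One fully contained read is therefore taken to add 25 bases, and coverage divided by 25 is called read equivalents. This length is an assumption, since reads of a larger multiple of 25 bases would also give such values. With longer reads the read equivalents would be too many and the counting intervals too narrow. Absolute values were used throughout. The deposited normalized coverage of a gene is its absolute value per 1000 of the library total, and the authors' deposited ratio is the quotient of the MS2-RyhB and the control normalized values, with no pseudocount. Recomputed quotients differed from it by at most 5.7e-06 of its size. Each column was assigned to its sample by its name, and no column of per-sample values was left unused.

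Total coverage was 215729862 bases for MS2-RyhB (8629194 read equivalents, 30 genes at 0) and 240616436 bases for the control (9624657 read equivalents, lowest value 2 bases). A design for read counts had been fixed before the data were examined, together with its rule for a table without counts, and that second rule was applied. Genes entered if the higher of their normalized values was at least the median of that quantity over non-zero genes, 0.0385 per 1000, which 2181 genes met. The pseudocount was the smallest non-zero value, 2 bases. Ratios were scaled so that the median gene past the minimum had a ratio of 1. The authors' ratio of that median gene was 3.72 (log2 1.90), so each fold given here lies that far below the authors' ratio on the log scale. Genes at or past 4-fold were counted in each direction.

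With 1 library per group there was no test, no p-value and no replicate check, and the ratios compare these libraries, not the conditions. Approximate 95% intervals (exact binomial, Clopper-Pearson) were computed from read equivalents. They cover counting error only, since PCR copies are not independent molecules, a read that crosses a gene border adds less than 25 bases, and differences between cultures or columns are not measured.

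For 21 gene lists fixed before the data were examined, the median log2 ratio was placed among those of 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile so obtained is limited to between 0.01 and 99.99. Genes of an operon move together, so the percentile was also computed with 1 value per run of same-strand genes at most 50 nt apart. This reduces the dependence but does not remove it. A run of a list took the mean of the list's own members, and a random run the mean of all its genes past the minimum. Percentiles by run therefore do not compare values built in the same way. An operon with wider gaps counts as more than 1 run, as the 13 genes of NADH dehydrogenase I did with 4. Adjacent same-strand genes over 50 nt apart still had a Spearman correlation of log2 ratios of 0.562. The text names ryhB and the 3 tRNA genes of the leuZ operon, the 20 highest and 10 lowest ratios outside rRNA genes, all known RyhB targets, up to 4 members with the highest and lowest ratios of each other list, and the 5 most abundant genes of each library. Genes named outside this rule, such as the members of the operons described, were chosen after their values were seen.

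Gene names are those of the deposited table. Of the names, 3842 matched a current symbol and 444 a synonym of the RefSeq genes of assembly ASM584v2, 4286 in all, and 76 did not match. That table served only for names, RNA classes and gene order. RyhB pairing energies were not computed, since no genome sequence was used here.

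The calculation was tested on simulated data drawn from the mean of both libraries with counting error only. With 200 genes changed, 100.0% of those made 6-fold or 16-fold higher and past the minimum were called at 4-fold, as were 93.9% of the genes made 6-fold lower. No 3-fold change was called, its recovered size being 2.94 upward and 2.93 downward. Of 1975 unchanged genes, 0 were called, and 95.1% of the intervals held the true fold. The changed genes were split evenly between the directions, and 1 depth factor applied to all genes. The scaling and the intervals were therefore not tested on libraries that differ as widely as these. Alternatives covered the scaling, the pseudocount, the minimum, the threshold and the use of 1 gene per operon. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.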

Results

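RNA bound to MS2 coat protein resin was sequenced from 1 culture expressing MS2-tagged RyhB and from 1 culture expressing RyhB without the tag. Each group therefore had 1 library, with 8629194 read equivalents for MS2-RyhB and 9624657 for the control. The comparison asks which RNAs were retained together with the tagged small RNA. Folds are given relative to the median of 2181 genes past the coverage minimum, and intervals in parentheses are 95% counting intervals. There were no replicates, so no difference between the libraries could be set against the spread between cultures.

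RyhB itself was 16.2-fold higher in the MS2-RyhB library (14.7 to 17.9), at 2.499 per 1000 of all coverage against 0.0414 in the control. In the authors' deposited table its ratio was 60.3. It ranked 54th among the genes past the minimum, and 53 genes had a higher ratio. Of all 2181 genes, 280 (12.8%) were at least 4-fold higher and 390 (17.9%) at least 4-fold lower, and 54 and 98 genes lay at least 16-fold higher and lower. The higher genes were 41.8% of all 4-fold calls. This split depended on the minimum and more strongly on the scaling. Without the minimum 327 genes were higher and 947 lower. The scaling factor was kept for that count, so the median log2 ratio was then -0.57 and not 0. With each library scaled to its total, as in the authors' ratio, 1049 genes were higher and 105 lower, 90.9% of calls being higher, because the median gene then stood at a log2 ratio of 1.90. Across genes, which are not independent replicates, the coverage of both libraries had a Spearman correlation of 0.464.

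**Figure D1:**
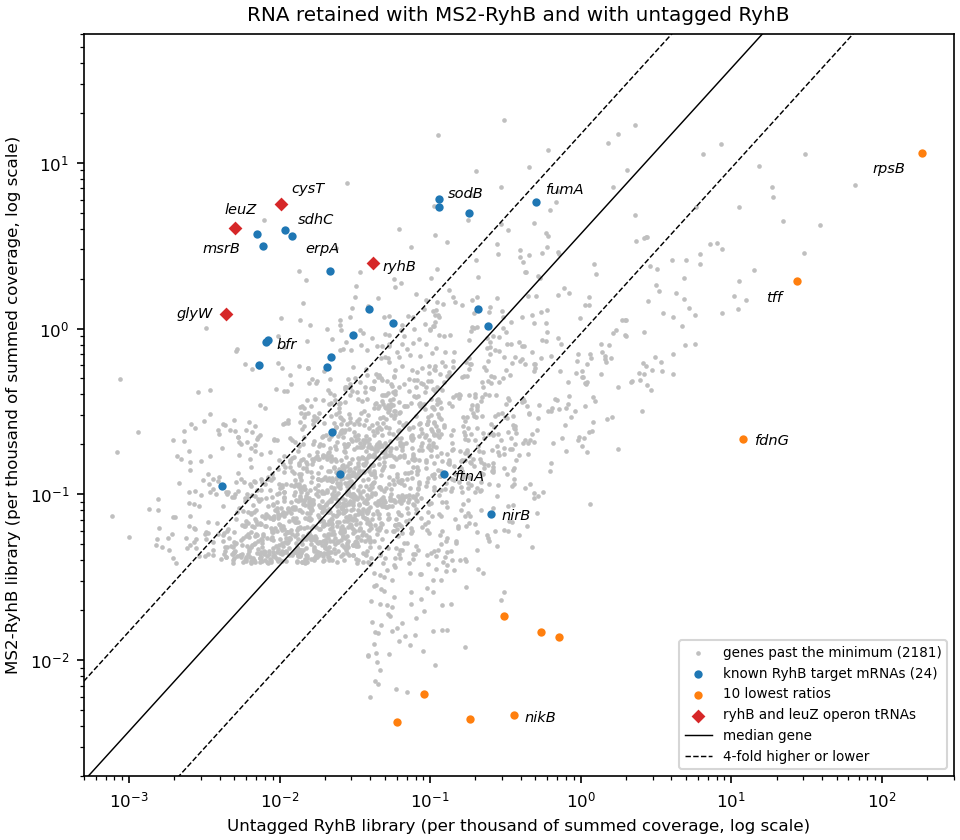
Normalized coverage of each gene past the minimum (per 1000 of summed coverage, log axes) in the untagged RyhB library (x) and the MS2-RyhB library (y). Each point is 1 gene, the solid line marks the median gene and the dashed lines 4-fold differences from it; ryhB and the leuZ operon tRNAs (diamonds) and most of the 24 known RyhB targets lie above the upper dashed line, and the 10 lowest ratios lie below the lower one.

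The highest ratio of all belonged to leuZ, a leucine tRNA gene, at 213-fold higher (160.1 to 286) and 4.01 per 1000 in the MS2-RyhB library. The other 2 tRNA genes of its operon, cysT and glyW, were 149.8-fold (122.7 to 184) and 74.1-fold higher (54.4 to 101.5). Together the 3 genes held 1.091% of the MS2-RyhB coverage and 0.002% of the control coverage. All 76 tRNA genes held 1.283% and 0.068%, so most of the tRNA coverage in the MS2-RyhB library came from this operon. The study's group had chosen this operon on these same samples, so the list is not independent evidence of its direction.

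Among the mRNAs, the highest ratios were those of the neighbours yeaC (155.7-fold) and msrB (141-fold, 111 to 182), which encodes methionine sulfoxide reductase B. The genes of the membrane anchor of succinate dehydrogenase followed, with sdhD 108.5-fold (86.2 to 137.5) and sdhC 96.5-fold higher (79.8 to 118). Next came yobH at log2 6.38, erpA at 6.31 and grxD at 6.18. The protein of erpA delivers iron-sulfur clusters, and grxD encodes a monothiol glutaredoxin. The rest of the 20 highest ran from ykgJ (5.84), yoaF (5.78) and bssS (5.47) through yciS (now lapA, 5.27), ugpB (5.26) and dadA (5.24) to rpsO, sodA and yncE (5.13 each). The gene ugpB encodes the glycerol 3-phosphate binding protein, dadA a D-amino acid dehydrogenase, rpsO ribosomal protein S15 and sodA the manganese superoxide dismutase. The values of ykgJ and yoaF rested on 8 and 11 control read equivalents.

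The noncoding RNA symR, which lies antisense to the toxin gene symE, reached 150.1-fold on 8 control read equivalents (81.0 to 370.4). It overlaps symE in the reference, and how the overlap was counted is not given in the sources used here, so its value is uncertain. The gene symE itself, below the minimum, stood at 2.06-fold (0.734 to 8.23).

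Known RyhB targets, a list of 24 mRNAs described as regulated by RyhB, had a median log2 ratio of 3.03 (quartiles 1.59 and 4.77). That median stood at the 99.99th percentile of random lists, the highest that 10000 lists can give, and the middle 95% of those lists ran from -1.64 to 0.47. With 1 value for each of 19 runs the median was 2.88, at the same percentile. Of the 24 genes, 17 were at least 4-fold higher, 1 was at least 4-fold lower and 6 lay between. On the authors' ratio the tally was 22 higher, 0 lower and 2 between. List percentiles are the same under both, since a single factor for all genes does not change their order. The list contributed 4 of the 20 highest genes, namely msrB, sdhD, sdhC and erpA. Of the 280 higher genes, 263 were not on it.

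Below those 4 genes, the positively regulated shikimate transporter gene shiA stood at 27.6-fold (22.2 to 35.0), close to sdhA (27.5-fold) and to bfr, which encodes bacterioferritin (27.3-fold). The gene sdhB followed at 22.3-fold, nuoA of NADH dehydrogenase I at 14.1-fold and sodB, the iron superoxide dismutase gene, at 12.7-fold (11.9 to 13.5). Log2 ratios from 3.17 down to 2.35 were found for iscS (3.17), iscU (3.05), nagZ (3.01), iscA (2.92), acnB (2.88), marA (2.87) and cysE (2.35). The targets that did not reach 4-fold were fumA (1.61), acnA (1.5), frdA (0.77), fur (0.49), cirA (0.21) and ftnA (-1.80), the last of which lies above 0 under the authors' scaling. The 1 target past 4-fold in the other direction was nirB, which encodes the large subunit of the NADH-dependent nitrite reductase and was 12.4-fold lower (11.4 to 13.5). On the authors' ratio nirB stood at -1.74 and no longer passed 4-fold.

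Iron-sulfur cluster assembly genes had a median of 3.05, and 9 of the 13 measured were at least 4-fold higher (12 on the authors' ratio) with none 4-fold lower. The list's percentile was 99.99, by gene and by run. Without the known targets on it, the 9 remaining genes had a median of 2.67. After erpA, the highest were nfuA (3.89) and sufA (3.79), and the lowest was sufD (-0.62). In the TCA cycle list 6 of 18 genes were higher (13 on the authors' ratio) and none lower, with a median of 1.20 (percentile 99.92, and 99.66 by run). The 11 members that are not known targets had a median of 0.14, and the lowest genes were mdh (-0.61) and aceA (-0.92). The 13 genes of NADH dehydrogenase I had a median of 0.45 (percentile 92.74), with 4 higher (7 on the authors' ratio). By run the percentile was 95.42, but there this 1 operon counted as 4 runs.

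**Figure D2:**
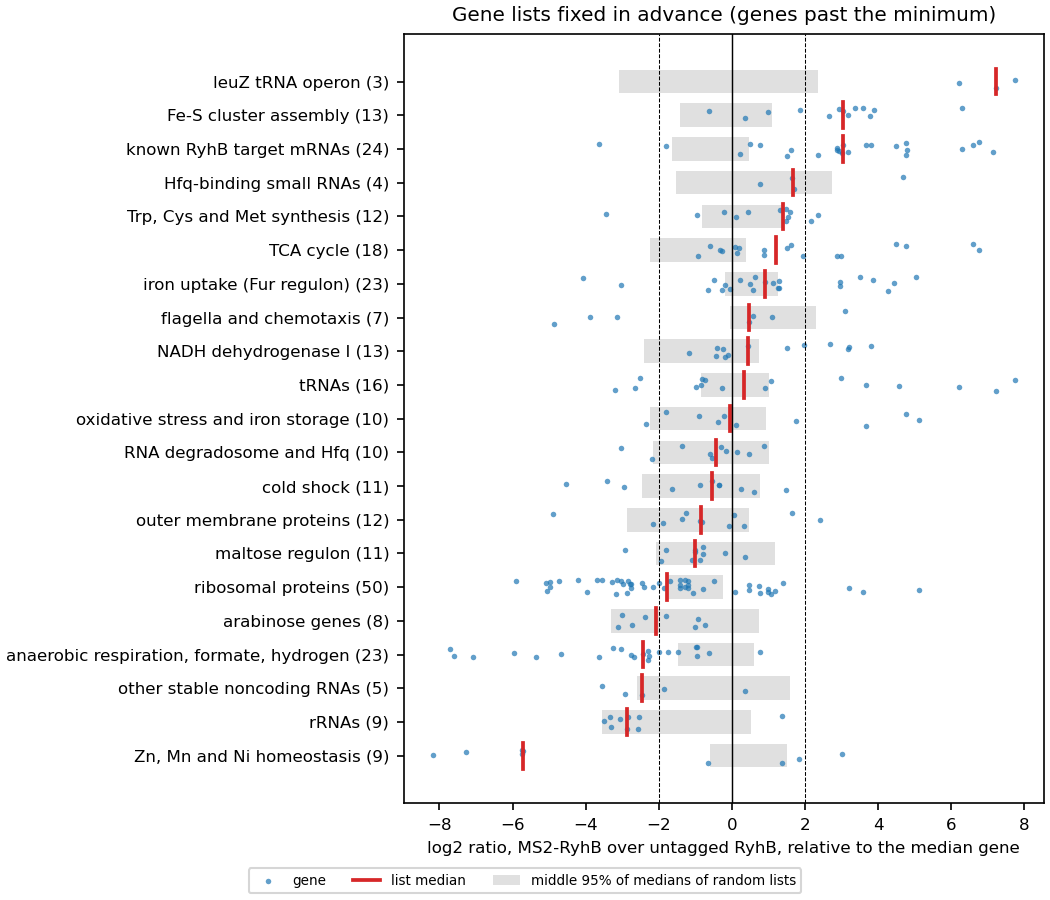
Log2 ratio of MS2-RyhB over untagged RyhB relative to the median gene (x) for the members past the minimum of 21 gene lists (y, number of genes in parentheses). Points are genes, red bars list medians, grey bars the middle 95% of medians of 10000 matched random lists and dashed lines 4-fold. The known RyhB targets (median 3.03), Fe-S cluster assembly (3.05), the leuZ operon (7.23) and the TCA cycle (1.2) lie right of their grey bars. So does, narrowly, tryptophan, cysteine and methionine synthesis (1.39). Anaerobic respiration (-2.42), zinc, manganese and nickel homeostasis (-5.71) and, narrowly, ribosomal proteins (-1.78) lie left.

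Within operons that hold known targets, the ratio differed between genes. From sdhC to sdhB it lay between 4.48 and 6.76, and in the sucABCD genes behind them between -0.27 (sucC) and 0.87 (sucA). Along the isc operon, which encodes the housekeeping cluster assembly system, iscR stood at 3.59 and hscB at 3.38. Behind these, hscA (1.86), fdx (0.98) and the last gene iscX (0.36) did not reach 4-fold. In the nuo operon, nuoA (3.82), nuoB (3.20), nuoF (3.17) and nuoG (2.70) were higher, nuoC (1.97) and nuoE (1.52) did not reach 4-fold, and the genes from nuoH to nuoN lay between -1.16 (nuoM) and 0.45 (nuoN). These steps past and short of 4-fold depended on the scaling. On the authors' ratio hscA (3.76), fdx (2.87), iscX (2.26), nuoC (3.87), nuoE (3.41), nuoN (2.35), sucA (2.77) and sucD (2.03) were past 4-fold, and nuoH to nuoM lay between 0.74 and 1.79. The order of the genes by ratio was not affected. The operons were chosen after their values were seen.

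**Figure D3:**
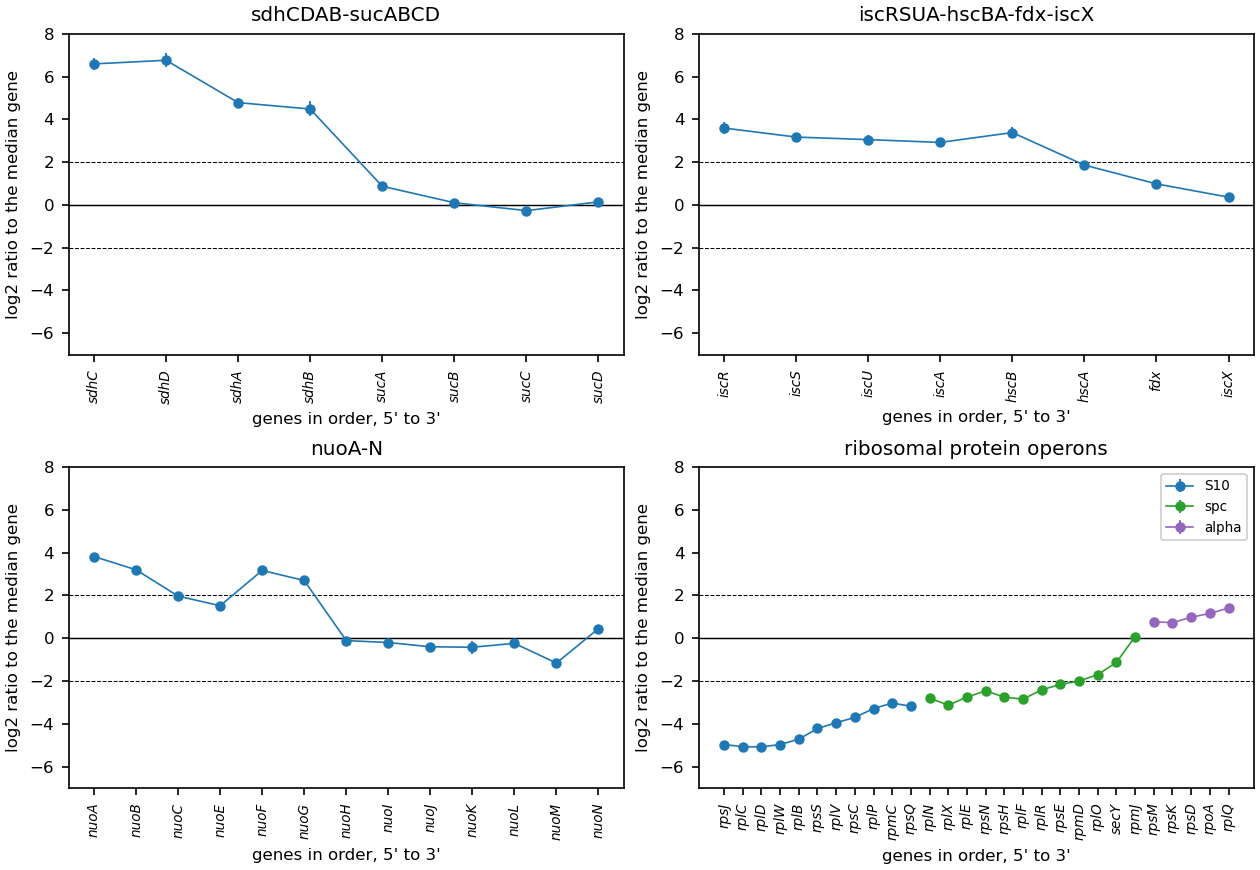
Log2 ratio relative to the median gene (y) for the genes of the sdh-suc, isc and nuo operons and of the S10, spc and alpha ribosomal protein operons, in gene order from the 5' end (x). Points are ratios, vertical bars 95% counting intervals, mostly smaller than the points, and dashed lines mark 4-fold; sdhC to sdhB lie at 4.48 or above and sucA to sucD at 0.87 or below.

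Iron uptake genes of the Fur regulon went both ways. Of 23 measured, 7 were at least 4-fold higher and 2 lower (16 and 1 on the authors' ratio), and the median of 0.90 stood at the 84.77th percentile (70.61 by run). The highest were fhuF (5.05), a ferric siderophore reductase gene, and entS (4.45), an enterobactin exporter gene. The ferrous iron transport genes feoA (-3.03) and feoB (-4.07) were lowest. Among 10 oxidative stress and iron storage genes, 3 were higher and 1, dps (-2.36), was lower (5 and 0 on the authors' ratio). The median was -0.05 (percentile 71.53), which turned to 1.85 under the authors' scaling. The list for tryptophan, cysteine and methionine synthesis had a median of 1.39 (percentile 97.80, and 97.28 by run), and 2 of its 12 genes, cysE (2.35) and cysJ (2.18), were 4-fold higher and cysN (-3.43) was lower. There were 9 higher and 0 lower on the authors' ratio. The median was 0.88 with a minimum of 500 reads combined and 0.05 with 20 reads or none.

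Of the 10 lowest ratios, 8 belonged to operons of anaerobic respiration or nickel uptake. The nickel transporter gene nikB was 289-fold lower in the MS2-RyhB library (212.5 to 407), with 40 read equivalents against 3474. In the same operon nikC, nikD and nikE stood at -7.28, -5.75 and -5.74. The formate dehydrogenase N genes fdnG (207-fold lower, 198 to 217), fdnH (194.7-fold) and fdnI (136.7-fold) and the nitrate reductase chaperone gene narJ (61.9-fold) were also among the 10 lowest. The remaining 2 were the ribosomal protein S2 gene rpsB, 60.1-fold lower, and its upstream neighbour tff, a noncoding RNA, 52.8-fold lower. Of 23 genes of anaerobic respiration and formate or hydrogen metabolism, none was 4-fold higher and 16 were 4-fold lower. Their median was -2.42 (percentile 0.07, and 0.37 by run), and -0.53 under the authors' scaling, with 6 lower and 1 higher. The highest member was frdA (0.77). Zinc, manganese and nickel genes had a median of -5.71 at the 0.01st percentile, but 5 of the 9 are the nik operon. By run the median turned to 1.37, at percentile 89.69, and by gene it was -3.71 with a minimum of 500 reads combined and -0.92 with 20 reads or none. Of the 9, 1 was higher and 5 lower, against 3 and 5 on the authors' ratio. The manganese importer gene mntH stood at 3.02 and znuA at 1.85.

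Highly abundant RNAs made up much of the control library. The 10 most abundant genes held 45.46% of its coverage, against 13.66% in the MS2-RyhB library. The gene rpsB alone held 18.57% of the control and 1.152% of the MS2-RyhB coverage, and the S10 ribosomal protein operon 14.866% and 1.957%. After rpsB, the most abundant in the control were rplC (33.6-fold lower in MS2-RyhB), rplD (33.9-fold), the 23S rRNA gene rrlA (10.1-fold) and tsf (39.7-fold), which encodes an elongation factor. In the MS2-RyhB library the most abundant were hns, a nucleoid protein gene 15.8-fold higher there, then rpsD (1.98-fold), rpoA (2.24-fold), rpsO (35.1-fold) and aspA (2.33-fold).

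Ribosomal protein genes as a list had a median of -1.78 (percentile 2.42), which turned to 0.12 with the authors' scaling, and by run the percentile was 34.89. Of the 50 genes, 24 were at least 4-fold lower and 3 at least 4-fold higher, namely rpsO and the neighbours rplU (12.01-fold) and rpmA (9.29-fold). By the authors' ratio, 8 were lower and 12 higher. Of 9 rRNA genes, 8 were lower (on the authors' ratio 0 lower and 1 higher), with a median of -2.86 (percentile 17.95), and the class held 5.047% of the MS2-RyhB and 10.283% of the control coverage. The 16S gene rrsA stood at 1.38 while the next highest, rrsC, stood at -2.55. These near-identical copies share reads, so single-copy values are uncertain.

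Among Hfq-binding small RNAs other than RyhB, 4 of 19 listed passed the minimum. Of these, chiX, listed under its older name sroB, was 25.6-fold higher on 7 control read equivalents, and cyaR (1.69), sroC (1.66) and gcvB (0.77) did not reach 4-fold. All 4 were 4-fold higher on the authors' ratio, where their median was 3.57. The list's median was 1.67 (percentile 79.52). Without the minimum, 2 of the 19 were higher and 3 lower, with a median of 0.35. Other stable noncoding RNAs had a median of -2.47 (percentile 3.29), and -0.57 under the authors' scaling. Of the 5, ssrA (-2.91), rnpB (-2.47) and the signal recognition particle RNA ffs (-3.54) were 4-fold lower, and csrB (0.37) was highest. The authors' ratio put 0 of them 4-fold lower and 1 higher. Of the 16 tRNA genes past the minimum, 6 were higher and 3 lower (8 and 0 on the authors' ratio), with a median of 0.33 (percentile 68.79, and 95.52 by run), the lowest being valX (-3.19) and valU (-2.65). The direction of this median depended on the minimum, as it was -0.26 with 500 reads combined, -0.53 with 20 reads and -0.65 with none.

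Lists chosen for contrast lay inside the middle 95% of random lists. The arabinose genes, whose inducer was the same in both cultures, had a median of -2.08 (percentile 31.35), with 4 of 8 lower and araG (-3.12) lowest. On the authors' ratio the median was -0.18, araG stood at -1.22 and none of the 8 was 4-fold lower. The maltose regulon had a median of -1.01 (percentile 19.01), with 1 of 11, malQ (-2.91), lower (on the authors' ratio 0 lower and 1 higher). Medians of -0.55 for cold shock genes (percentile 58.05), -0.84 for outer membrane protein genes (66.33) and -0.43 for RNA degradosome genes and hfq (56.59) were found, and all 3, like that of the maltose regulon, turn positive under the authors' scaling. Their lowest members were deaD (-4.54), tolC (-4.89) and rne (-3.04), the gene of RNase E. The outer membrane protease gene ompT (2.40) was past 4-fold. Of the cold shock, outer membrane and degradosome genes, 3, 2 and 2 were 4-fold lower, against 1, 1 and 0 on the authors' ratio, where 3 of each list were higher. The 7 flagella and chemotaxis genes past the minimum had a median of 0.47 (percentile 17.47), from cheA (-4.88) to flgA (3.11), the 1 member at least 4-fold higher, and 3 were lower. The authors' ratio put 4 higher and 1 lower, with a median of 2.36. The median of 0.47 turned negative with other minimums, to -1.33 (500 reads combined), -1.75 (20 reads) and -1.87 (none).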

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

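Scaling had the largest effect on the counts, and the alternatives for the scaling factor over all genes, for totals without 10 control genes and for a minimum of 100 reads were chosen after the data were seen. The 280 higher and 390 lower genes became 1049 and 105 with library totals or the authors' ratio as deposited, and 1018 and 115 with totals that leave out ryhB, rRNA and tRNA genes. They became 663 and 197 with totals without the 10 genes of most control coverage, and 437 higher (294 lower) with the factor taken over all genes with coverage in both libraries. In the same 4 scalings the log2 ratio of ryhB moved from 4.02 to 5.91, 5.85, 5.14 and 4.57. The known-target median moved from 3.03 to 4.92 and 4.86 with totals and with totals lacking ryhB and stable RNA, and to 4.15 and 3.58 with the added scalings. The median of the ribosomal protein genes turned from below to above a ratio of 1. It was 0.12 with totals or the authors' ratio and 0.06 with totals without ryhB, rRNA and tRNA. It stayed below the median gene, which stood at 1.90 and 1.84 in these scalings. These shifts follow from the scaling itself, which moves the median gene by up to 1.90. Lower counts also grew with lower minimums, to 602 (100 reads combined), 810 (20 reads) and 947 (no minimum), as more genes entered. The higher counts grew less, to 306, 324 and 327. Without a minimum the median log2 ratio was -0.57 on the main scaling, so the genes left out by the minimum ran lower. The split and the median gene used for scaling therefore depend on the minimum. At 2-fold there were 606 higher and 653 lower genes, and at 10-fold 103 and 164. Upper-quartile scaling (302 and 369), a pseudocount of 5 reads (268 and 388), no pseudocount (280 and 390), a minimum of 500 reads (265 and 397) and a count by the interval's nearer bound (219 and 367) stayed within 1.5 times. The known-target median was 2.88 with 1 gene per operon. Of 561 values of 51 single genes under the alternatives, 258 moved beyond the counting interval and 303 did not. The 303 include the values under other minimums, which leave the ratio of a single gene unchanged by construction. Library totals and the authors' ratio are the same scaling but were counted separately. The tally is therefore no measure of stability. The sign changed in 3 values of 1 gene, ftnA, which was not past 4-fold and went from -1.80 to 0.10 with totals or the authors' ratio and to 0.04 with totals without ryhB, rRNA and tRNA. In all, 8 list medians changed sign under some alternative, those of tRNA and flagella genes with the minimum and the other 6 with the scaling. RyhB pairing energies and their alternatives were not run. No paired analysis was possible because each group has 1 library, and no library could be left out. Depth limits genes with few control reads, such as symR and ykgJ, whose upper bounds exceed their ratios by more than 2-fold.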

Other observations

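The tests of oxygen-regulated genes without neighbours of genes already seen, of scaling, of counting error, of the most abundant control genes and of stable RNA were chosen after the values they use were seen, and the oxygen list was written after the data were first seen but before its values were tabulated. Outside the known targets, several neighbouring genes had high ratios together, and they were picked after their values were seen. The D-amino acid dehydrogenase gene dadA (37.9-fold higher) is followed by dadX, an alanine racemase gene, at 27.8-fold (21.3 to 36.6). The gene yciS (38.6-fold) is followed by yciM at 26.6-fold (22.5 to 31.7), both linked to lipopolysaccharide assembly. Along the ribosomal protein operons the ratio was higher toward the 3' end, though not at every step. It went from -4.97 (rpsJ) to -3.18 (rpsQ) in the S10 operon, from -2.80 (rplN) to 0.08 (rpmJ) in the spc operon and from 0.77 (rpsM) to 1.41 (rplQ) in the alpha operon. Under the authors' scaling each value lies 1.90 higher, so the order stays and the signs of rplO (-1.70) and secY (-1.13) change.

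Genes linked to oxygen regulation, regulators such as fnr included, were mostly lower in the MS2-RyhB library when outside the lists already described. Of 28 such genes, 19 were at least 4-fold lower and 1, narP (2.92), was higher, with a median of -3.23. The genes nrdG and ccmG were left out because their low ratios had already been seen, and with them 21 of 30 were lower and the median was -3.30. On the authors' ratio 9 of the 28 were 4-fold lower and 5 higher, with a median of -1.33. The lower genes included nrdD, the anaerobic ribonucleotide reductase (25.6-fold lower), the nitrate transporter narK (23.5-fold), pflB, pyruvate formate-lyase (20.2-fold), the formate channel focA (16.4-fold) and the threonine catabolism genes tdcA to tdcD (7.02-fold to 14.7-fold). The genes cydA (-0.80) and hypB (-0.72) were near the median gene, but cydB, the neighbour of cydA, was 5.24-fold lower. The regulators fnr (1.61) and arcA (-2.50) lay on opposite sides of the median gene.

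The first pattern is the low ratio of the 12 fdn, nar and nik genes (median -5.85, from -8.18 to -2.69). Scaling on the median gene does not account for it, since the median of the authors' own ratio over these genes was -3.96, and counting error is too small, as the highest upper bound of the 12 ratios was 0.16. The other oxygen-regulated genes stood at percentile 0.01 of random lists, by gene and by run, the smallest value 10000 lists can give, and still did so, with a median of -2.92 over 24 genes, without nrdD, ccmF, ccmH and narK, which neighbour genes seen before. Cultures that differed in the expression of such genes would give this pattern. Neither library measures RNA before the column, so retention and abundance in the culture cannot be told apart. That limit holds for the higher genes and the known targets as well. The known target nirB (-3.63) is itself on the anaerobic respiration list. An effect of the tagged against the untagged small RNA on the low transcripts stays open and untested, because each group has 1 culture.

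The second pattern is that the median gene stood at log2 1.90 in the authors' ratio, with 1780 of 2181 genes above 1. Leaving the 10 genes with the most control coverage out of both totals lowered it to 1.12, so these 10 genes may account for 0.78 of it. How much abundant control RNAs account for in all cannot be told, since leaving out more genes was not tested. The 100 most abundant genes of each library held 79.12% of the control and 48.31% of the MS2-RyhB coverage. Leaving out rRNA and tRNA lowered it to 1.83 only. Whether the remainder reflects a broader retention of RNA with the tagged bait or a different makeup of the control eluate was not tested.

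The third pattern is that ratios were shared along transcripts. Across genes, which are not independent replicates, log2 ratios of adjacent same-strand genes at most 50 nt apart had a Spearman correlation of 0.869 (590 pairs). For adjacent same-strand genes over 50 nt apart it was 0.562 (521 pairs), and for adjacent genes on opposite strands, at any spacing, 0.099 (395 pairs). The first and last of these differ in spacing as well as in strand. The difference of 0.77 is consistent with retention or expression of whole polycistronic RNA, which the test does not separate. DNA carry-over or copy number that varies along the genome would act on both strands alike. The opposite-strand value of 0.10 argues against it as the source of the shared ratios. Carry-over spread evenly over the genome need not make neighbours alike, so this comparison cannot address it. Reads that cross gene borders are also an insufficient explanation, since genes of a run with 1 gene between them exceeded the opposite-strand value by 0.64.

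No preference for the start of a run was detectable, but few runs entered and the random ranges were wide. Only runs with gaps of at most 50 nt and every gene past the minimum were used. An operon with wider gaps was cut up, as the nuo operon was into 4 runs, so a trend along whole operons was not tested. Among 11 runs of at least 4 genes that hold a gene 4-fold higher, the highest gene lay nearer the 5' end in 7, against 5.3 in random orders (2 to 8). Among 15 runs with a gene 4-fold lower, the lowest gene did so in 7, against 7.2 (3 to 11).

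The gene ynjH held place 2 in the authors' deposited table with a ratio of 635.0, on 68 read equivalents in the MS2-RyhB library and 3 bases of coverage in the control, less than 1 read. It was below the coverage minimum and is not counted among the higher genes.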
